A study of Homo sapiens with 6 samples.

How the data were processed

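The data are RNA-seq libraries of U2OS cells, 3 treated for 4 h with 0.05% DMSO and 3 with 5 µM NMS-873, each a separate sample in the labels and grouped by its title. Per the labels' protocols, a stranded kit for polyadenylated RNA was used, genomic DNA was removed in an extra round of extraction, and the 6 libraries were pooled and sequenced with single reads on 1 flow cell. Spike-in RNA is not mentioned in the labels, but the deposited table holds 92 rows of ERCC spike-in transcripts, 80 of them with a read.

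The submitters deposited 1 table with 57912 rows. Its sample columns hold FPKM values per the file headers, here reads per gene scaled by gene length and by a size factor of each library, described below. The table also holds the mean normalised count of each gene over the libraries, a signal in units of reads after scaling, and the log2 fold change and the adjusted p-value of the submitters' own comparison, all as deposited. Per the submitters' processing notes, the build was hg19 and the tools include featureCounts 1.5.1 and DESeq2 1.16.1; the aligner is not given in the sources used here, nor is whether counting used strand.

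The design fixed before the data were examined assumed normalised counts, and the sample columns hold FPKM, so normalised counts were rebuilt: the FPKM values of a gene were multiplied by its deposited mean normalised count and divided by its mean FPKM. Multiplied by the size factor that the table implies for each library, 100% of the rebuilt values came within 0.001 of a whole number of reads, and the largest distance was 1.3e-09. The implied size factors equal the median of ratios over the spike-in rows, with a largest relative difference of 3.1e-15, so the deposited values are scaled to the spike-in RNA. With this scaling a change in the RNA content of the cells would move all genes, and an error in the amount of spike-in RNA would do so too. Rebuilt reads in genes came to 21142319, 22281422 and 22488952 for DMSO replicates 1 to 3 and 21132311, 22188004 and 21438199 for NMS-873 replicates 1 to 3. Reads carry no molecular identifiers, so counting error is a lower limit on the error.

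Genes with a mean normalised count of at least 10 over the 6 libraries (14889 of 57820, of which 27709 had a read) were tested with limma 3.58.1 in R 4.3.3 on log2(normalised count + 1), with treatment as the only term, an intensity trend in the prior variance, two-sided tests and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Fold changes are on the log2(normalised count + 1) scale, which understates the changes of low genes. The 25 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation beside it, and with fry, and adjusted over the 25 lists. In addition, the members of each list were adjusted over the list alone. Of the list members, 1 was not matched to a row and was not analysed here. For symbols on more than 1 row the row with the larger mean was used. The deposited unit is FPKM, so limma on log values was kept as the test. The submitters' tool and edgeR were not run here, and of tests on the rebuilt reads voom was run.

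Genes were named by a rule set before the data were examined: 9 genes always (VCP, UFD1L, NPLOC4, MYC, ATF4, DDIT3, ATF3, XBP1, HSPA5); the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean normalised count of at least 50 and all 3 libraries of one treatment on the same side of all 3 of the other; and in each list the up to 3 members with the lowest adjusted p among those past the threshold. Other genes are said to have been named after their values were seen. Some genes, among them ones that this rule selects, are not reported here. Coordinates are those of the deposited table, build hg19. Gene types came from GENCODE 29 by gene identifier, for 14561 of the tested genes, and none of its coordinates are used.

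The analysis was tested on simulated data drawn from the mean of each gene over the 6 libraries and the libraries' size factors, with 50 genes changed at each fold size among 14889. At 1.5-fold 78% of them were recovered, at 2-fold 90% and at 4-fold 100%, and 8 of 14649 unchanged genes were called. Of 24 simulated lists of random unchanged genes 0 passed camera with the preset correlation. The simulation drew genes independently and gave every gene the same spread beyond counting error (dispersion 0.00126). It therefore does not test lists whose genes vary together, and in the real lists the estimated correlations lay between 0.0354 and 0.984. The authors' deposited table gives an adjusted p under 0.05 for 5501 genes, 1857 higher and 3644 lower. Of these, 5446 were among the genes tested here, and 5408 were called here too, all with the same sign. Replicates were checked for duplicates: the chi-square per degree of freedom of their reads lay between 1.53 and 7.96 within treatments, so none agreed within sampling noise. Correlations between log2 profiles were at least 0.995 within treatments and at most 0.985 between them. Alternatives covered the pseudocount, the count minimum, the scaling, the replicate block, the variance model, the thresholds, the set test and leaving out each library. TMM factors were computed from their definition, not with edgeR. The alternatives added after the data were seen were gene-based size factors, voom on the rebuilt reads and log2(FPKM + 0.1). Voom and log2(FPKM + 0.1) kept the spike-in scaling of the main result. Figures were drawn with matplotlib 3.10.9.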

Results

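Polyadenylated RNA was sequenced from U2OS cells, an established human osteosarcoma cell line, after 4 h with 5 µM NMS-873 or with 0.05% DMSO, the solvent. NMS-873 is an allosteric inhibitor of VCP (also called p97), an ATPase that pulls ubiquitylated proteins out of membranes and complexes so that the proteasome can degrade them. There were 3 libraries per treatment, and each held between 21132311 and 22488952 reads in annotated genes. The 6 libraries also carried ERCC spike-in RNA, a set of synthetic transcripts added in known amounts, which took 0.359% to 0.386% of the reads. A mean normalised count of at least 10 was reached by 14889 of the 57820 annotated genes, and these were tested. The comparison asked how the transcripts of these cells responded when VCP was inhibited. The study's title links VCP to K6-linked ubiquitin chains and to MYC, so genes of both were among the 25 lists chosen before the data were examined. The p-values of lists below are from camera with a preset correlation unless said otherwise. Adjusted over the list alone, the counts per list were the same as over all genes tested except where another count is given.

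With NMS-873, genes of the integrated stress response, of protein folding in the endoplasmic reticulum (ER) and of sterol synthesis were higher, and genes of mitosis were lower. With an estimated correlation between genes the stress response and sterol lists passed the set test, and the ER chaperone and mitosis lists did not (adjusted p = 0.0941 and adjusted p = 0.484). The largest rise was that of DDIT3, which encodes the stress transcription factor CHOP: its level was 199 ± 11.9 normalised counts with DMSO and 6884 ± 266 with NMS-873, a 34.4-fold difference (means ± SD, n = 3 libraries each, as for the levels below). ATF3, another stress transcription factor, rose 16.2-fold, from 372 ± 8.48 to 6041 ± 124 normalised counts. HSPA5, the main ER chaperone (BiP), rose 6.78-fold, from 26462 ± 907 to 179406 ± 8506 normalised counts, and XBP1, a transcription factor of the unfolded protein response, rose 3.79-fold. ATF4, which encodes the activator of the integrated stress response and is controlled mainly at translation, rose 1.92-fold at the transcript level.

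Of the 14889 genes tested, 7127 (47.9%) passed an adjusted p of 0.05 in limma, 2217 higher and 4910 lower with NMS-873. Most changes were small: the median size among the calls was 0.35 on the log2 scale, and 573 calls changed at least 2-fold, 244 of them higher and 329 lower. The excess of lower calls depends on the scale. The deposited values were scaled to the spike-in RNA, and on that scale the median gene was at -0.10 (log2); when the libraries were scaled to the genes instead, a choice made after the data were seen, the median gene was at 0.00 and the split was 3760 higher and 3108 lower. With TMM factors it was 3920 higher and 2952 lower, and after quantile normalisation 3087 higher and 4114 lower. Scaling to equal totals, which uses no spike-in RNA, kept the excess, with 2472 higher and 5320 lower and the median gene at -0.10. Changes close to -0.10 are therefore changes of the typical gene on the spike-in scale and with equal totals. The labels do not say whether the libraries of a treatment came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. For each gene this spread was estimated mostly from genes of similar level, because limma's prior variance had 250.84 degrees of freedom. A gene whose own libraries varied more could therefore pass, as MT-ND1 did although its groups overlapped. Without the variance trend 5507 genes passed.

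**Figure D1:**
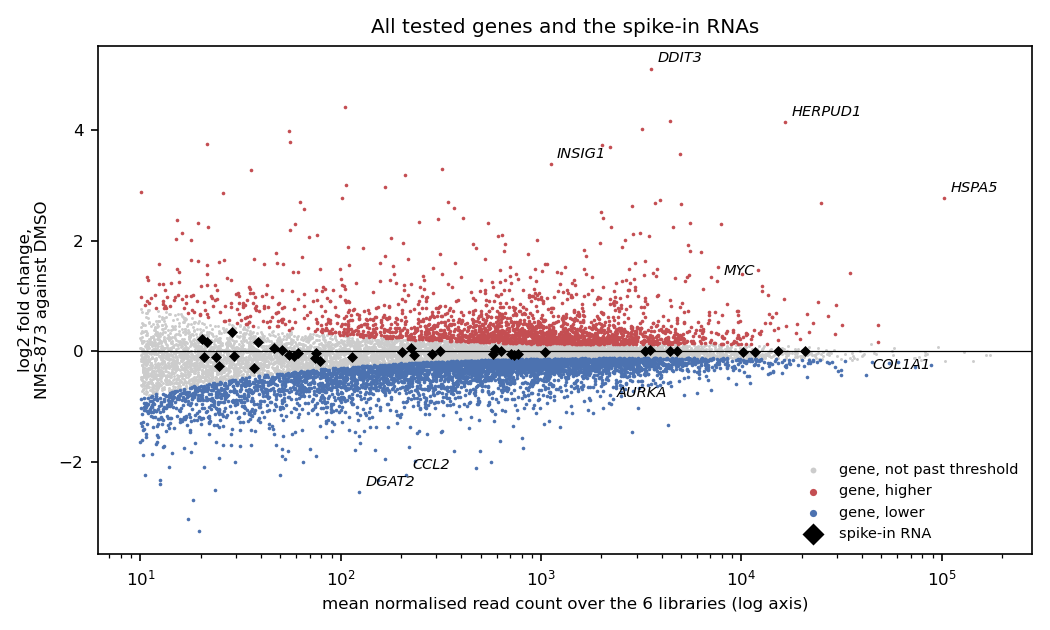
Each point is 1 of the 14889 tested genes, with its mean normalised read count over the 6 libraries on a log axis and its log2 fold change, NMS-873 against DMSO, on the vertical axis; red points are the 2217 genes called higher, blue points the 4910 called lower, and black diamonds the 38 spike-in RNAs with a mean of at least 20. DDIT3 stands highest, HSPA5 combines a high level with a 6.78-fold rise, and the spike-in RNAs lie around 0 with a median of -0.01.

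The target itself changed little. VCP (ENSG00000165280.11; chromosome 9, 35056061 to 35073246, hg19) was at 18070.3 ± 662 normalised counts with DMSO and 21095 ± 174 with NMS-873, a 1.17-fold rise (log2 fold change 0.22, SE 0.0617, adjusted p = 0.00122). UFD1L (chromosome 22, 19437433 to 19466738) and NPLOC4 (chromosome 17, 79523913 to 79615495), the cofactors that bring VCP to ubiquitylated proteins, did not pass the test: UFD1L was at 4094 ± 212 normalised counts with DMSO and 4029 ± 66.0 with NMS-873 (log2 fold change -0.02, adjusted p = 0.762) and NPLOC4 at 6166 ± 290.4 normalised counts with DMSO and 5784 ± 162 with NMS-873 (log2 fold change -0.09, adjusted p = 0.157). In the list of VCP and its cofactors, 10 of 30 tested members rose and 5 fell, with a median log2 fold change of 0.02. The members with the lowest adjusted p were ZFAND2A, an arsenite-inducible zinc finger protein, which rose 2.35-fold, WAC, which rose 1.47-fold, and UBXN7, which rose 1.27-fold. The list passed at adjusted p = 0.0232, and adjusted p = 0.843 with an estimated correlation. With gene-based factors 16 rose and 1 fell, and with TMM factors 19 rose and 1 fell, with medians of 0.12 and 0.13. The list no longer passed with fry (adjusted p = 0.0637), with a count minimum of 50 (adjusted p = 0.0922), or when any library except NMS-873 replicate 1 was left out, with adjusted p between 0.0518 and 0.0772. The lower calls numbered 2 without DMSO replicate 1 or NMS-873 replicate 1, and 3 without DMSO replicate 3 or NMS-873 replicate 2. Among the ubiquitin genes and the enzymes that make or remove K6-linked chains, 4 of 14 rose and 4 fell, 7 and 0 with TMM factors, and the list did not pass (adjusted p = 0.182). Lower calls numbered 2 without DMSO replicate 1, DMSO replicate 3 or NMS-873 replicate 1, and higher calls 2 without DMSO replicate 2. RNF144B, a ubiquitin ligase, rose 1.65-fold, and USP8, a deubiquitylase, rose 1.15-fold. RNF144B was low and its groups overlapped, at 37.5 ± 15.5 normalised counts with DMSO and 59.7 ± 16.6 with NMS-873.

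The integrated stress response list moved almost entirely one way. Of its 38 tested members, 37 rose and 1 fell, with a median log2 fold change of 1.05 and adjusted p = 7.14e-84, and adjusted p = 0.0185 with an estimated correlation. DDIT3 (chromosome 12, 57910371 to 57914300) and ATF3 (chromosome 1, 212738676 to 212794119) led it, with DDIT4, an inhibitor of mTORC1 signalling, which rose 17.9-fold from 467 ± 36.6 to 8350.1 ± 336 normalised counts. CHAC1, a glutathione-degrading enzyme, rose 13.2-fold from 284 ± 14.4 to 3759 ± 56.3 normalised counts, and SESN2, a stress-induced sensor of leucine, rose 11.8-fold. ATF4 (chromosome 22, 39915700 to 39918691) was at 11220.5 ± 440.2 normalised counts with DMSO and 21487 ± 777 with NMS-873. TRIB3, a pseudokinase and a target of CHOP, rose 6.18-fold, and the single member that fell was ATF5, 1.46-fold lower; both were named after their values were seen. Of the 20 cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 11 rose and 1 fell: CARS rose 1.81-fold, AARS 1.74-fold and SARS 1.63-fold, while RARS, named after its value was seen, fell 1.1-fold. With gene-based factors 15 rose and 0 fell. That list passed with the preset correlation and not with an estimated one (adjusted p = 5.46e-07, and adjusted p = 0.539 with an estimated correlation).

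**Figure D2:**
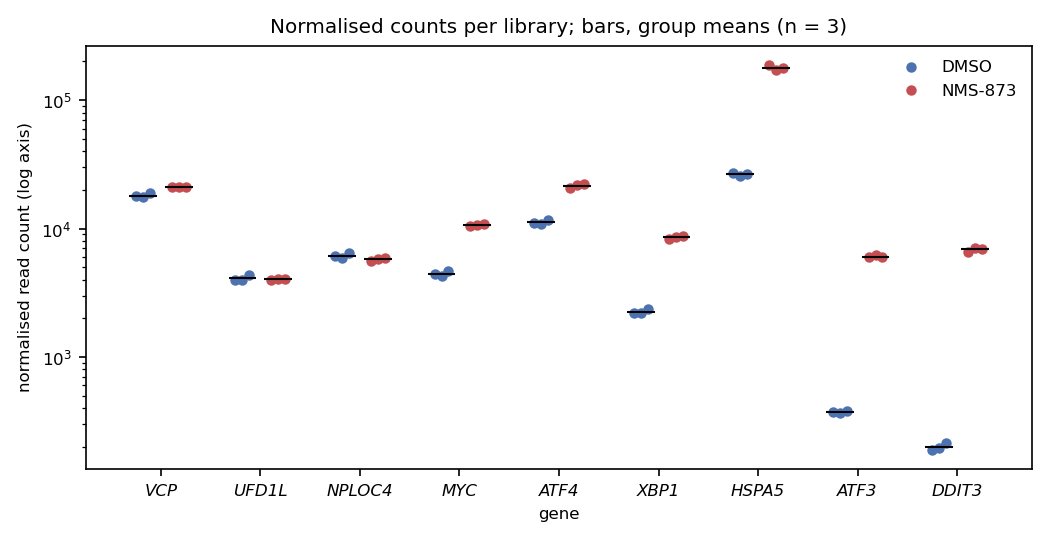
Normalised read counts of 9 genes on a log axis, with 1 point per library, blue for DMSO and red for NMS-873, and a bar at each group mean (n = 3). The libraries of the 2 treatments lie far apart for DDIT3, ATF3, HSPA5 and XBP1, nearer for ATF4 and MYC, and close together for VCP, UFD1L and NPLOC4.

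Genes of ER protein folding rose together. Of 26 tested ER chaperones and folding enzymes, 21 rose and 1 fell, with a median log2 fold change of 0.54 and adjusted p = 1.34e-36, and adjusted p = 0.0941 with an estimated correlation. HSPA5 lies on chromosome 9, 127997132 to 128003609. Of the other members, SDF2L1, part of an ER chaperone complex, rose 5.29-fold, and DNAJC3, a co-chaperone of BiP, rose 4.32-fold. DNAJB9, another BiP co-chaperone, rose from 315 ± 16.0 to 4094 ± 238 normalised counts, and the 1 member that fell was FKBP7, at 1.23-fold lower (named after its value was seen). XBP1 (chromosome 22, 29190543 to 29196585) was at 2251 ± 92.0 normalised counts with DMSO and 8530.2 ± 229.5 with NMS-873. With gene-based factors 24 chaperones rose and 0 fell. In ER-associated degradation, the route by which VCP extracts misfolded ER proteins, 14 of 26 tested members rose and 3 fell (15 higher and 4 lower adjusted over the list alone; adjusted p = 5.77e-12, and adjusted p = 0.179 with an estimated correlation). With gene-based factors 18 rose and 1 fell. HERPUD1, an organiser of the degradation complex, rose 17.6-fold, from 1774 ± 74.7 to 31315 ± 671 normalised counts, and the ubiquitin ligase SYVN1 and its partner SEL1L rose 3.89-fold and 2.65-fold. The members that fell were EDEM3, UBE2G2 and TMEM129, at log2 fold changes of -0.16, -0.27 and -0.23, named after their values were seen. Of 35 genes of ER to Golgi transport and translocation, 20 rose and 1, KDELR3 (named after its value was seen), fell (21 higher and 1 lower adjusted over the list alone; adjusted p = 1.74e-06, and adjusted p = 0.642 with an estimated correlation), 29 and 0 with gene-based factors, led by SEC24D and SEC23B, coat proteins of vesicles leaving the ER, at 2.4-fold and 1.5-fold, and by SRPRB, a subunit of the signal recognition particle receptor, at 1.34-fold.

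Genes of sterol synthesis and uptake also rose. Of 26 tested members, 22 rose and 1 fell, with a median log2 fold change of 1.49, and this list passed both ways (adjusted p = 1.75e-65, and adjusted p = 0.0185 with an estimated correlation). MSMO1, an enzyme of the late cholesterol pathway, rose 6.68-fold, from 1022 ± 37.1 to 6827 ± 139 normalised counts. INSIG1, which holds the sterol sensor SCAP in the ER, rose 10.4-fold, from 194 ± 15.5 to 2036 ± 71.9 normalised counts, and STARD4, a sterol carrier, rose 6.39-fold. HMGCS1, an early enzyme of the pathway, rose 6.38-fold, while PMVK was 1.22-fold lower; these members were named after their values were seen.

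The heat shock and proteasome lists did not show such a rise. Of 27 tested members of the heat shock list 8 rose and 6 fell, and the list did not pass (adjusted p = 0.371). It did with gene-based factors, where 14 rose and 5 fell (adjusted p = 0.0437), and with TMM factors (adjusted p = 0.0374). Besides cytosolic heat shock proteins, the list holds chaperones of mitochondria and of the ER and heat shock transcription factors, which these counts include. HSPB8 rose 1.33-fold, and DNAJB2 and CRYAB fell 1.59-fold and 1.27-fold. BAG3 and DNAJB1, which rise strongly in a heat shock response, were 1.26-fold and 1.22-fold higher, and HSPA1A and HSPA1B were at log2 fold changes of 0.20 and 0.06, which is uncertain because their sequences are nearly identical; these members were named after their values were seen. Of 33 proteasome subunits 0 rose and 2 fell, PSMB6 by 1.15-fold and PSMD1 by 1.09-fold (0 higher and 1 lower adjusted over the list alone; adjusted p = 0.824 for the list), and with gene-based factors 9 rose and 0 fell. With TMM factors 10 rose and 0 fell, with equal totals 2 rose and 9 fell, and after quantile normalisation 3 rose and 10 fell. At an unadjusted p under 0.05 in limma, 1 rose and 4 fell, and with voom 0 rose and 2 fell. Without DMSO replicate 3, 2 rose, and without NMS-873 replicate 1, 3 rose and 0 fell. Of 19 NRF2 targets 3 rose and 7 fell, 5 and 1 with gene-based factors (adjusted p = 0.427). The number that fell was 2 without DMSO replicate 1, DMSO replicate 3 or NMS-873 replicate 1, and 3 without NMS-873 replicate 2. HMOX1, heme oxygenase, rose 1.59-fold, GCLC, which makes the glutathione precursor, 1.44-fold, and TXNRD1 1.38-fold. Of 29 autophagy and lysosome genes 11 rose and 1 fell (adjusted p = 0.00199, and adjusted p = 0.693 with an estimated correlation). With gene-based factors 17 rose and 1 fell. They included WIPI1 at 2.08-fold, MAP1LC3B, which encodes the autophagosome marker LC3B, at 1.73-fold, and ATG13 at 1.38-fold.

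**Figure D3:**
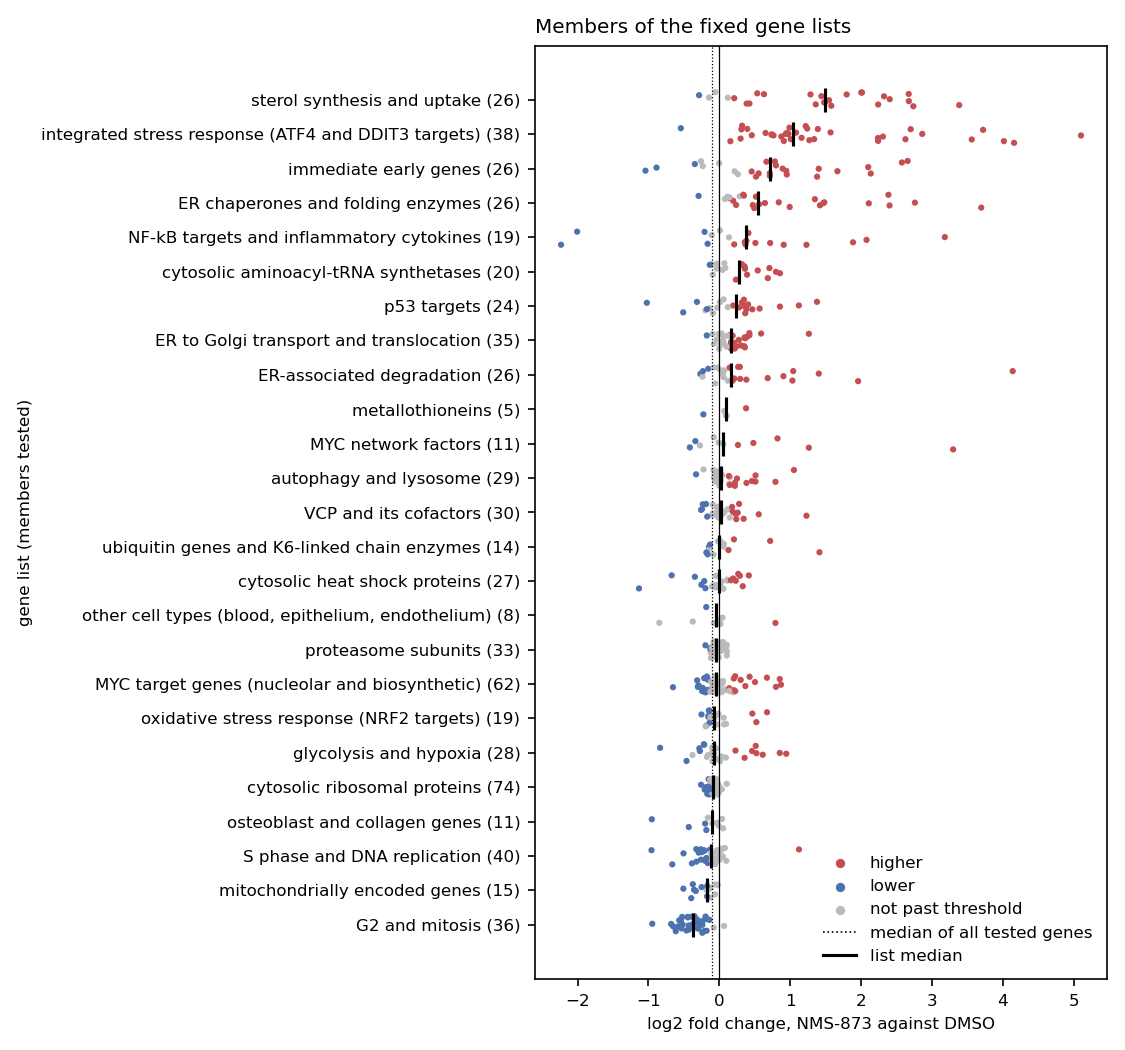
Each point is a tested member of 1 of the 25 gene lists, with its log2 fold change, NMS-873 against DMSO, on the horizontal axis (red, higher; blue, lower; grey, not past the threshold); black bars mark list medians, and the dotted line marks the median of all tested genes, -0.10. The sterol and integrated stress response lists have the highest medians, 1.49 and 1.05, and the G2 and mitosis list the lowest, -0.37.

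MYC (chromosome 8, 128747680 to 128753674) was at 4453 ± 232 normalised counts with DMSO and 10687 ± 253 with NMS-873, a 2.4-fold rise (log2 fold change 1.26, SE 0.0549, adjusted p = 6.65e-62). Of 11 tested members of the MYC network list, which holds MYC and factors that bind with or against it, 5 rose, MYC among them, and 2 fell (adjusted p = 2.25e-04, and adjusted p = 0.193 with an estimated correlation). The median log2 fold change was 0.06 against a mean of 0.46, so a few members moved far and the list did not move as a whole. MXD1, which competes with MYC for its partner MAX, rose 9.85-fold, from 58.4 ± 4.26 to 583 ± 12.1 normalised counts, and MNT, another repressor that binds MAX, rose 1.77-fold; MAX and MXD4 rose 1.4-fold and 1.2-fold, and MXD3 and MGA fell 1.33-fold and 1.26-fold, the last 4 named after their values were seen. The MYC target genes split: 14 of 62 rose and 15 fell, and the list did not pass (adjusted p = 0.182). With gene-based factors the count was 24 and 7 and the list passed upward (adjusted p = 0.0214), as it did with TMM factors (adjusted p = 0.0156). TMEM97, HK2 and RCL1 had the lowest adjusted p and rose 1.83-fold, 1.81-fold and 1.74-fold; TMEM97 is also a sterol-responsive gene, and HK2 also stands in the glycolysis list. Of 74 ribosomal protein genes 0 rose and 14 fell (0 higher and 4 lower adjusted over the list alone), a direction that turned with gene-based factors, at 8 higher and 3 lower. With TMM factors 11 rose and 2 fell, with equal totals 1 rose and 28 fell, and after quantile normalisation 1 rose and 43 fell. The list did not pass (adjusted p = 0.371), though it passed downward after quantile normalisation (adjusted p = 6.16e-05). At an unadjusted p under 0.05 in limma, 0 rose and 20 fell, and with voom 0 rose and 17 fell. The count that fell was 3 without DMSO replicate 3, 4 without NMS-873 replicate 1 and 7 without DMSO replicate 1, and 3 without the variance trend. RPS26, RPS25 and RPL35 were 1.2-fold, 1.15-fold and 1.14-fold lower.

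Genes of mitosis fell. Of 36 G2 and mitosis genes 34 fell and 0 rose, with a median log2 fold change of -0.37, and 30 fell with gene-based factors. The counts were also 34 and 0 at an unadjusted p under 0.05 in limma and with voom. The test gave adjusted p = 3.74e-12, and adjusted p = 0.484 with an estimated correlation. AURKA, a kinase of the spindle poles, fell 1.93-fold, from 2935 ± 147 to 1524 ± 104 normalised counts, PLK1, a mitotic kinase, fell 1.57-fold, and BUB1B, a checkpoint kinase, fell 1.6-fold. The members that did not pass were CDC25C and BUB3, at 0.07 and -0.08 (log2; named after their values were seen). Of 40 S phase and DNA replication genes 1 rose and 18 fell, 8 and 15 with gene-based factors, and the list did not pass (adjusted p = 0.0898) although it did after scaling to equal totals (adjusted p = 0.0131), after quantile normalisation (adjusted p = 7.35e-04), without a count minimum (adjusted p = 0.00271) and on log2(FPKM + 0.1) (adjusted p = 0.0477). CDC6, a loader of the replicative helicase, rose 2.18-fold, and E2F2 and ORC1 fell 1.94-fold and 1.58-fold. Of 24 p53 targets 13 rose and 4 fell (13 higher and 6 lower adjusted over the list alone; adjusted p = 2.09e-04, and adjusted p = 0.484 with an estimated correlation): CDKN1A, the cell cycle inhibitor p21, rose 2.6-fold, from 3039.6 ± 207 to 7894 ± 369 normalised counts, PLK3 rose 2.18-fold, and PLK2 fell 2.03-fold. The others that fell were TP53I3, POLH and DDB2, named after their values were seen.

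Signalling genes that respond within hours rose in most cases. Of 26 immediate early genes 18 rose and 3 fell (18 higher and 4 lower adjusted over the list alone; adjusted p = 3.83e-20, and adjusted p = 0.179 with an estimated correlation). DUSP1, a phosphatase of MAP kinases, rose 6.31-fold, from 1364 ± 77.8 to 8607 ± 224 normalised counts, EGR1 rose 4.4-fold and BTG1, an antiproliferative factor, 4.29-fold, whereas EGR3, KLF10 and IER5 were 2.06-fold, 1.85-fold and 1.27-fold lower (named after their values were seen). EGR3 was low and its groups overlapped, at 17.2 ± 6.62 normalised counts with DMSO and 8.77 ± 5.74 with NMS-873. Of 19 NF-kB targets and cytokines 12 rose and 4 fell (13 higher and 4 lower adjusted over the list alone; adjusted p = 3.30e-07, and adjusted p = 0.408 with an estimated correlation). With gene-based factors 14 rose and 2 fell, and with fry the list did not pass (adjusted p = 0.0784). IL8 and IL11, secreted cytokines, rose 4.22-fold and 3.7-fold, and PTGS2, the inducible cyclooxygenase, rose 9.08-fold, from 40.7 ± 6.38 to 376 ± 37.5 normalised counts. CCL2, a chemokine that attracts monocytes, fell 4.7-fold, from 348 ± 7.23 to 73.3 ± 1.69 normalised counts, and CSF2, a growth factor of myeloid cells, fell 4.02-fold; the other members that fell were BIRC3 and SOD2, whose calls were both lost without DMSO replicate 3. CSF2, BIRC3 and SOD2 were named after their values were seen.

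Among glycolysis and hypoxia genes 8 of 28 rose and 6 fell (adjusted p = 0.12), with the glucose transporter SLC2A3 at 1.93-fold and NDRG1 at 1.53-fold. Of 11 osteoblast and collagen genes 4 fell and 0 rose (0 higher and 3 lower adjusted over the list alone; adjusted p = 0.37), with gene-based factors 2 fell and 1 rose, and with voom or at an unadjusted p under 0.05 in limma 4 fell and 0 rose. Without NMS-873 replicate 2, 2 fell, and with fry the list passed downward (adjusted p = 0.0322). The members that fell included RUNX2, the main transcription factor of bone-forming cells, which fell 1.94-fold, COL1A1, a chain of type I collagen, which fell 1.35-fold, and COL5A1, which fell 1.14-fold. Of 5 tested members of the metallothionein list, SLC30A1, a zinc exporter, rose 1.3-fold and MT1E fell 1.17-fold (adjusted p = 0.37). Of 15 mitochondrially encoded genes 8 fell and 0 rose (0 higher and 9 lower adjusted over the list alone), 5 and 0 with gene-based factors, and the list did not pass (adjusted p = 0.0799). At an unadjusted p under 0.05 in limma, and with voom, 10 fell and 0 rose; without the variance trend 1 fell, and with a robust prior or on log2(FPKM + 0.1) 2 fell. MT-ND6 fell 1.42-fold, MT-ND1 1.32-fold and MT-ND3 1.26-fold. The count depended on single libraries. In NMS-873 replicate 1, mitochondrial genes took 3.99% of the reads in genes against 2.66% and 2.50% in the other NMS-873 libraries: without it, 15 fell and the list passed (adjusted p = 1.86e-05). Without DMSO replicate 3, 12 fell and it passed too (adjusted p = 0.0057), and without any one of the other 4 libraries 5 fell. It also passed with voom (adjusted p = 0.0216), without a count minimum (adjusted p = 0.0151) and after quantile normalisation (adjusted p = 0.0408). Markers of blood, epithelium and endothelium reached the count minimum for 8 of 20 genes; VWF, an endothelial protein, rose from 20.1 ± 2.29 to 36.4 ± 11.1 normalised counts and KRT8, a keratin, fell 1.14-fold (adjusted p = 0.798).

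Among genes with a mean normalised count of at least 50, the 10 largest rises were those of DDIT3, DDIT4, HERPUD1, ATF3, IL1A, CHAC1, DNAJB9, SESN2 and 2 non-coding genes, RP11-325K4.3 and RP11-325K4.2. IL1A, the cytokine interleukin 1 alpha, rose 15.8-fold, from 7.31 ± 6.76 to 103 ± 15.2 normalised counts, a log2 fold change of 3.978 that was 3.389 without DMSO replicate 2, 4.615 without DMSO replicate 3 and 2.771 with a pseudocount of 10. RP11-325K4.3 and RP11-325K4.2 lie inside HERPUD1 on its strand, so their reads may be those of HERPUD1 and their values are uncertain. The largest fall was that of DGAT2, which makes triglycerides, at 5.84-fold, from 212 ± 13.9 to 35.5 ± 3.25 normalised counts (chromosome 11, 75470557 to 75512579). FAM46A fell 5.01-fold, from 257 ± 26.7 to 50.3 ± 4.41 normalised counts, and the related FAM46B 4.33-fold. BMP4, a secreted growth factor, fell 3.99-fold, HES1, a target of Notch signalling, 3.95-fold, BHLHE41, a repressor of the circadian clock, 3.87-fold, PDE4B, a cyclic AMP phosphodiesterase, 3.83-fold, GNB3 4.01-fold and HOXB6 3.72-fold; CCL2 completed the 10. The rule took only genes in which all 3 NMS-873 libraries lay on the same side of all 3 DMSO libraries. Over all tested genes 53.6% were separated in this way, against 10% by chance. Some named genes overlap another gene in the annotation, among them DDIT3 with MARS, DNAJB9 with PNPLA8 and THAP5, GNB3 with CDCA3, and HOXB6 with HOXB3; whether reads were counted by strand is not given in the sources used here, so part of their reads may belong to the partner.

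Of the 25 lists 13 passed with the preset correlation, 12 upward and 1 downward, and 2 with an estimated correlation, the integrated stress response and sterol lists. With fry, which weighs a list by itself, 12 passed: the lists of VCP cofactors and of NF-kB targets no longer did, and the osteoblast list did. The camera test weighs a list against the other genes, whose median was below 0. In the heat shock, proteasome, ubiquitin, MYC target, NRF2, glycolysis and other cell type lists, none of which passed, the median was below 0 while the test's direction was upward.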

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

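Under the alternatives run, the count of changed genes stayed within 1.5 times of 7127 except with a fold threshold. The genes called were not all the same. Of the 7127 main calls, 5168 were kept with TMM factors, 5324 with gene-based factors and 5257 without the variance trend. No main call passed with the opposite sign. TMM and gene-based factors could hardly give such a call, since they moved the median gene only from -0.10 to 0.01 and 0.00 (log2). Requiring at least a 2-fold change left 573 genes, 244 higher and 329 lower. The higher and lower counts moved with some of the scalings: 3920 and 2952 with TMM factors, and 3760 and 3108 with gene-based size factors, which were chosen after the data were seen, as were voom and log2(FPKM + 0.1). TMM and gene-based factors center the typical gene. After quantile normalisation the counts were 3087 and 4114, and with equal totals 2472 and 5320, an excess of lower calls close to that of the main result (68.28% against 68.89% lower). Leaving out each library in turn gave 5975 to 6835 changed genes, 1870 to 2406 higher and 4005 to 4957 lower, with 12 to 14 lists passing. With an estimated correlation 2 lists passed in place of 13. The only named gene that changed sign past the threshold was UFD1L, at 0.0915 (log2, adjusted p = 0.0317) with TMM factors; its main value did not pass. Of 125 genes selected by the naming rule or named later, 98 kept their call under every alternative, and 19 of 25 lists did so apart from the estimated correlation and fry. With fry 12 lists passed, and 3 differed: VCP and its cofactors (adjusted p = 0.0637), NF-kB targets (adjusted p = 0.0784) and osteoblast genes (adjusted p = 0.0322). Leaving out 1 library ended calls of small changes. It also ended those of RNF144B, EGR3 and VWF, low genes with larger log2 fold changes of 0.72, -1.04 and 0.79. Without DMSO replicate 1 the calls of PSMD1, COL5A1, RARS and EDEM3 ended, and without DMSO replicate 2 those of USP8 and EDEM3. Without DMSO replicate 3 those of PSMD1, RNF144B, FKBP7, KDELR3, RARS, EGR3, BIRC3 and SOD2 ended. Without NMS-873 replicate 1 those of PSMB6, PSMD1, RARS, MXD4, EGR3 and SOD2 ended. Without NMS-873 replicate 2 those of PSMD1, COL5A1, VWF, FKBP7, RARS, HSPA1A and EDEM3 ended, and without NMS-873 replicate 3 those of PSMD1 and TMEM129. Adjusted p then lay between 0.0522 and 0.268.

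The same replicate number did not clearly pair the libraries: the correlations of their deviations were 0.13, -0.05 and 0.15, and 4 of 6 libraries correlated best with their own number, not every one. So few libraries cannot exclude a pairing. With a replicate block 7607 genes were called, 2352 higher and 5255 lower, and 12 lists passed, without that of VCP and its cofactors (adjusted p = 0.0543). The edgeR quasi-likelihood test, the same with the block, and DESeq2 were planned for recovered reads and were not run, and voom on the rebuilt reads was run in their place. Depth limits small changes in low genes: of simulated 1.5-fold changes 42.2% were recovered at mean counts under 100 and 99.8% at 100 or more, and with 0.5 of the reads 15.5% and 97.2%.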

Other observations

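Of 143 gene families grouped by the start of their symbols, a grouping made after the data were seen, 7 passed with camera's preset correlation: DUSP, ATF, SEC, HSPA, KDM and KLF upward and HIST downward. ATF, SEC, HSPA and KLF also share members with the fixed lists. In HSPA, 4 of 11 members rose and 2 fell, and the family includes the ER chaperone HSPA5 (log2 fold change 2.76). With an estimated correlation adjusted p was 1 for each of the 7. Of 13 tested HIST genes, which encode histones, 10 fell and 0 rose (11 and 0 at an unadjusted p under 0.05 in limma), with a median log2 fold change of -0.50 (adjusted p = 0.00381). HIST1H2AC fell 2.04-fold, from 1228 ± 49.6 to 603 ± 34.0 normalised counts. The kit was for polyadenylated RNA, so these values cover only the polyadenylated transcripts of histone genes and not their total transcripts. Of the DUSP phosphatases 8 of 17 rose and 3 fell, 5 of the 17 also being in the immediate early list (adjusted p = 0.000858). With TMM or gene-based factors, equal totals, quantile normalisation and voom the medians of these 2 families kept their sign. Of single genes named after their values were seen, CCND1, cyclin D1, fell 2.53-fold, from 6158 ± 278 to 2436 ± 121 normalised counts; AXIN2, a target of WNT signalling, fell 2.59-fold; and PTCH1, the receptor and target of Hedgehog signalling, fell 2.7-fold.

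The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 7127 genes (2217 higher and 4910 lower) and the highest of the other splits called 0 with limma, or 380 at an unadjusted p under 0.05. For the lists, 7 of the 10 splits passed as many as the real one (13), and the highest other passed 17. Each of the other splits sets 2 libraries of a treatment against 1 and so keeps part of the treatment difference, so list passes in them do not measure chance. The rest of that difference adds to the spread within their groups, so their 0 gene calls do not measure chance either. For the shift to lower values and for the non-coding genes, the tests were chosen after the result was seen, except that on neighbouring genes.

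More genes were lower than higher on the spike-in scale, and an error in the amount of spike-in RNA would move every gene alike. Coding genes with mean counts of 10 to 100 shifted further than coding genes at 3000 or more, by -0.161 (log2, SE 0.0289 over libraries). Such an error cannot give this difference. The low coding genes themselves shifted by -0.212 (SE 0.0249), so an error of this kind can account for part of their fall at most. With the libraries scaled to equal totals, which uses no spike-in RNA, the abundant coding genes shifted by -0.0479 (SE 0.0137). Such an error cannot enter this value, which therefore shows a fall in their share of the reads and does not test whether an error occurred. On the spike-in scale the abundant coding genes shifted by -0.0516 (SE 0.0403), and for their amount against the spike-in RNA an error and a real change cannot be told apart, because the shift is close to the spread between libraries (spike-in share of reads 0.373% ± 0.0137% with DMSO and 0.374% ± 0.00791% with NMS-873; SD, n = 3). Reads taken up by the genes that rose would lower the other genes and the spike-in RNA alike. The further shift of the low coding genes (-0.161, SE 0.0289) argues against this as the whole cause of their fall. For the fall of abundant genes as a share of the reads it stays open, as does the treatment itself, and neither was tested further.

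Long non-coding genes lay lower than coding genes, with median log2 fold changes of -0.34 for lincRNA and -0.34 for antisense genes against -0.09 for coding genes. The shares called lower were close, at 36.9%, 35.9% and 33.2%, and the shares called higher differed more, at 5.3%, 3.2% and 16.3%. Low abundance accounts for part of the lower medians at most, since the difference was -0.245 (SE 0.00939 over libraries) and at matched abundance still -0.145 (SE 0.0137). Genomic DNA is argued against by reads in 401 olfactory receptor genes, 43 of which had a read in any library. Pooled over the libraries of both treatments, they put its share in the median non-coding gene at no more than 0.123%. The rate in the DMSO libraries alone was not measured. Reads from neighbouring genes are argued against by 288 non-coding genes with no tested gene within 5 kb, which differed from coding genes by -0.135 (SE 0.0184). A faster turnover or lower synthesis of unstable transcripts after VCP inhibition is a candidate explanation and was not tested.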
